A study of Mus musculus with 6 samples.

How the data were processed

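RNA was sequenced from hearts of male mice aged 8 or 9 weeks, in 3 ground control libraries (1 g; GC1 to GC3) and 3 lunar gravity libraries (LG1 to LG3). Per the labels' protocols, the lunar gravity mice were kept at 0.167 g on the International Space Station in a centrifuge of 15 cm radius turning at 31 rpm, and the ground controls, of the strain C57BL/6J, numbered 6 per mission. The labels name a strain for the ground controls alone, give no mission for a library, and do not say that each library is a separate mouse, so p-values measure the spread between libraries, in which technical and biological parts are not told apart. Per the same protocols, RNA was extracted with ISOGEN II, about 500 ng was depleted of ribosomal RNA, and libraries were sequenced on an Illumina NextSeq 500. No flight group at 1 g was analysed here, so the comparison joins gravity with everything else that differed between station and ground.

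The authors deposited 1 table of 49585 genes with 161 columns. Its genome is GRCm38 (mm10), per the submitters' processing notes. The aligner, the counter, the annotation release and the use of strand are not given in the sources used here. Per the file headers the table holds, for each library, an expression value, exon, exon-exon and intron read counts, and RPKM. The deposited expression values are whole read counts, and in all 49585 genes they equal, exactly, the unique exon reads plus the multi-mapped exon-exon reads. The deposited RPKM values equal total exon reads over exon length and 1 constant per library in 97.7% of values (relative tolerance 1e-6), and were not tested. Genes annotated with 0 exons, 17474 in number, have an expression value of 0 in every library. The deposited comparison gives a p-value, an adjusted p-value and a signed fold change (a score, positive where the PG columns were higher), per the file headers. Those headers place GC3 under PG, so that the deposited comparison sets 2 libraries against 4. The name and title of GC3 call it a ground control, and that grouping was used here. Coordinates are those of the deposited table, counted from 1. Of its genes, 49326 matched GENCODE M21 identifiers, and 45128 had the same start and end there. Gene types and GC content came from GENCODE M21.

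Total counts ranged from 6461213 to 8271553 per library. Replicates of a group differed by more than counting noise, with a chi-square per gene of 2.07 to 6.06, so no library was treated as a copy of another. Genes were filtered with filterByExpr (a minimum count of 10), scaled by TMM and tested with edgeR 4.0.16 (quasi-likelihood fit, robust) in R 4.3.3, which left 12258 genes. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called changed at an adjusted p under 0.05. CPM values are scaled by TMM. Standard errors are the log2 fold change over the root of the edgeR F statistic. Robust fitting gives genes of unusual spread fewer degrees of freedom, so a small standard error can go with a larger p. The biological coefficient of variation was 6.20%.

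In all, 53 gene lists were fixed before the data were examined: 28 of function, 23 of cell type and 2 of RNA quality. The 45 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with the correlation estimated for each list, and with fry, from limma 3.58.1. Camera compares a list with the other genes, while fry tests whether a list's own genes move, on balance, one way. Members were counted with p adjusted over all genes and adjusted over the list alone. The genes named were fixed by a rule, also before the data were examined. Its first part took the 12 largest rises and the 12 largest falls among changed genes whose groups did not overlap, with a mean of at least 1 CPM in the higher group, leaving out predicted genes, Riken names and clone identifiers. The second took up to 3 changed members of each function list by p, or the member with the smallest p where none changed. The third was a fixed panel of 12 cardiac genes, and the fourth took up to 4 changed members of each cell type or quality list. These gave 94 genes. Genes with under 50% of their exon reads placed uniquely are pointed out. Overlapping and antisense genes are uncertain in general, since the use of strand is not stated.

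The tests were tried on simulated data. Among 12136 simulated genes for this comparison, edgeR recovered 30% of 50 genes changed 1.3-fold, 60% of those changed 1.5-fold, 88% at 2-fold and 94% at 4-fold, and 6.21% of its calls were false. DESeq2 recovered 24%, 50%, 78% and 94% of the same genes, with 1.60% false calls. Alternatives were RLE, upper quartile and total-count scaling, other filters, DESeq2 1.42.0, limma voom, non-robust fitting, a replicate block, mitochondrial and ribosomal RNA genes left out, other thresholds, other read columns, removal of length and GC content trends (loess span 0.5), and leaving out each library. DESeq2's independent filtering gave no adjusted p to 6417 of the 12258 genes, which are counted neither as calls nor as lost calls. The planned filter of 1 CPM in every library of a group tested 12409 genes, more than filterByExpr, so a filter of 5 CPM was added after the data had been seen. A first fit of the planned design and the intron shares had been seen before the added alternatives were chosen. Alternatives planned for a table without counts did not apply.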

Results

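Hearts of male mice kept at lunar gravity (0.167 g) in a centrifuge aboard the International Space Station were compared with hearts of ground control mice (1 g), to ask how RNA levels in the heart differed between these settings. RNA depleted of ribosomal RNA was sequenced in 3 libraries per group, called GC1 to GC3 (ground control) and LG1 to LG3 (lunar gravity). Total counts were 6461213, 7209653 and 6987320 in GC1 to GC3 and 7780281, 7095862 and 8271553 in LG1 to LG3. Mitochondrially encoded genes took 16.3% to 18.3% of the counts. Levels are CPM (counts scaled to a common library size) as mean ± SD (n = 3), fold changes are lunar gravity over ground control unless called lower, and adjusted p-values are from edgeR's quasi-likelihood test unless another tool is named. Of 86 named genes called changed, 83 lost the call when GC3 was grouped with lunar gravity, as the header of the deposited table places it against its title, and 19 lost it with DESeq2 without independent filtering. Where a library is named as left out, the adjusted p is the largest among the fits that lost the call.

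In lunar gravity, some chaperones of the endoplasmic reticulum and the slow myosin gene Myh7 rose, while some genes of cell division and of the extracellular matrix fell, as did the muscle genes Ttn and Myh6. Of 12258 genes tested, 462 changed, with 191 higher and 271 lower. Most changes were small: 78.1% of the changed genes differed by under 1.5-fold and 43 by 2-fold or more. The groups did not overlap in 99.6% of the changed genes and in 20.6% of all tested genes, where chance gives 10%. The changed genes were called from the same values, so their 99.6% is no separate evidence. Genes of a library are not independent, and 20.6% was not tested against 10%. Among 622 tested genes of the function lists, 90 changed. Of 45 lists tested with camera at a preset correlation, 10 shifted, 4 up and 6 down. Splits that mixed the groups shifted 1 to 13 lists at that correlation, so the count of 10 does not set the real grouping apart. With an estimated correlation no list passed camera, and 7 had an unadjusted p under 0.05. Fry called 3 lists: cell division (fry adjusted p = 0.015), extracellular matrix and ribosomal protein genes (0.044 each). It did not call endoplasmic reticulum stress (0.076) or immediate early genes (0.12). The count of changed genes was 219 without GC2, 232 without LG2 and 32 under the deposited grouping of GC3. When libraries were scaled by their totals in place of TMM, 59.9% of the calls were higher, against 41.3%.

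Genes of the endoplasmic reticulum stress list had 8 of 19 tested members higher and none lower. The list holds chaperones and other folding factors of that compartment, beside stress regulators such as the transcription factors Atf4, Ddit3 and Atf3. The 8 were Hsp90b1, Hspa5, Pdia6, Manf, Sdf2l1, Calr, Pdia4 and Dnajb9, so Atf4, Ddit3 and Atf3 were not among them. Adjusted over the list alone, 11 were higher. Hsp90b1, the HSP90 chaperone of this compartment (ENSMUSG00000020048, chromosome 10, 86690209 to 86705509), rose from 338 ± 30.1 to 571 ± 19.4 CPM, a log2 fold change of 0.75 (SE 0.060, adjusted p = 6.16e-08). Hspa5, the chaperone BiP, rose 1.48-fold (adjusted p = 1.63e-06), and the disulphide isomerase Pdia6 rose 1.53-fold (adjusted p = 8.40e-06). Sdf2l1, a cofactor of BiP, rose 2.22-fold, from 6.03 ± 1.57 to 13.3 ± 2.38 CPM (adjusted p = 7.25e-04). The median log2 fold change of the list was 0.41 and its camera adjusted p was 1.29e-19, but adjusted p = 0.26 with an estimated correlation. Over all alternatives its adjusted p ranged from 7.75e-26 to 0.35, the latter under the deposited grouping of GC3. Heat shock and chaperone genes of the cytosol and mitochondria had no member changed among 16 by edgeR (1 lower when adjusted over the list alone), with 4 at an unadjusted p under 0.05 and 0 by DESeq2 or limma voom. The smallest p was that of Hspd1, a mitochondrial chaperone, at a log2 fold change of -0.19 (adjusted p = 0.067). Hspd1 passed without LG3 (adjusted p = 0.040), without a filter (0.045) and with the exon length trend removed (0.047). The heat shock list passed toward lower without GC3 (camera adjusted p = 1.22e-04, against 0.21 with all libraries; 2 members lower) and under the deposited grouping of GC3 (1.89e-07).

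Cell division genes had 9 of 22 tested members lower and none higher, with 11 lower and 1 higher when adjusted over the list alone. Mki67, a marker of cycling cells (ENSMUSG00000031004, chromosome 7, 135689784 to 135716361), fell from 18.3 ± 3.43 to 3.66 ± 0.845 CPM, a log2 fold change of -2.31 (SE 0.19, adjusted p = 6.16e-08). Top2a, a topoisomerase of dividing cells, was 7.65-fold lower (adjusted p = 1.17e-06), and the cyclin gene Ccna2 was 5.19-fold lower (adjusted p = 9.22e-04). The mitotic motor Kif11 was 4.19-fold lower. Among the 12 largest falls, 5 were members of this list. Outside it were Iqgap3, the spindle gene Aspm, the mitotic transcription factor Foxm1, the condensin gene Ncaph, the linker histone Hist1h1b and Uhrf1, at 3.28-fold to 6.73-fold lower. Rtn4r, the Nogo receptor gene, was 2.95-fold lower (adjusted p = 1.88e-04). Apart from Mki67 and Rtn4r, at 10.6 CPM, the 12 genes lay at or below 8.92 CPM on the ground. The list's median log2 fold change was -0.89 and its camera adjusted p was 3.58e-18, but adjusted p = 0.060 with an estimated correlation, in a range from 1.04e-30 to 0.060 over all alternatives. DESeq2 gave an adjusted p to only 1 of the 22 members because of its filter on mean count, and called none; without that filter it called 4, and limma voom called 9. The list had 5 members lower without GC2. Calls were lost by Cdk1 (without GC2, GC3 or LG2; 0.093), Ncaph (GC2 or LG3; 0.062), Hist1h1b (GC2, LG2 or LG3; 0.19) and Uhrf1 (GC2, LG1 or LG2; 0.099).

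**Figure D1:**
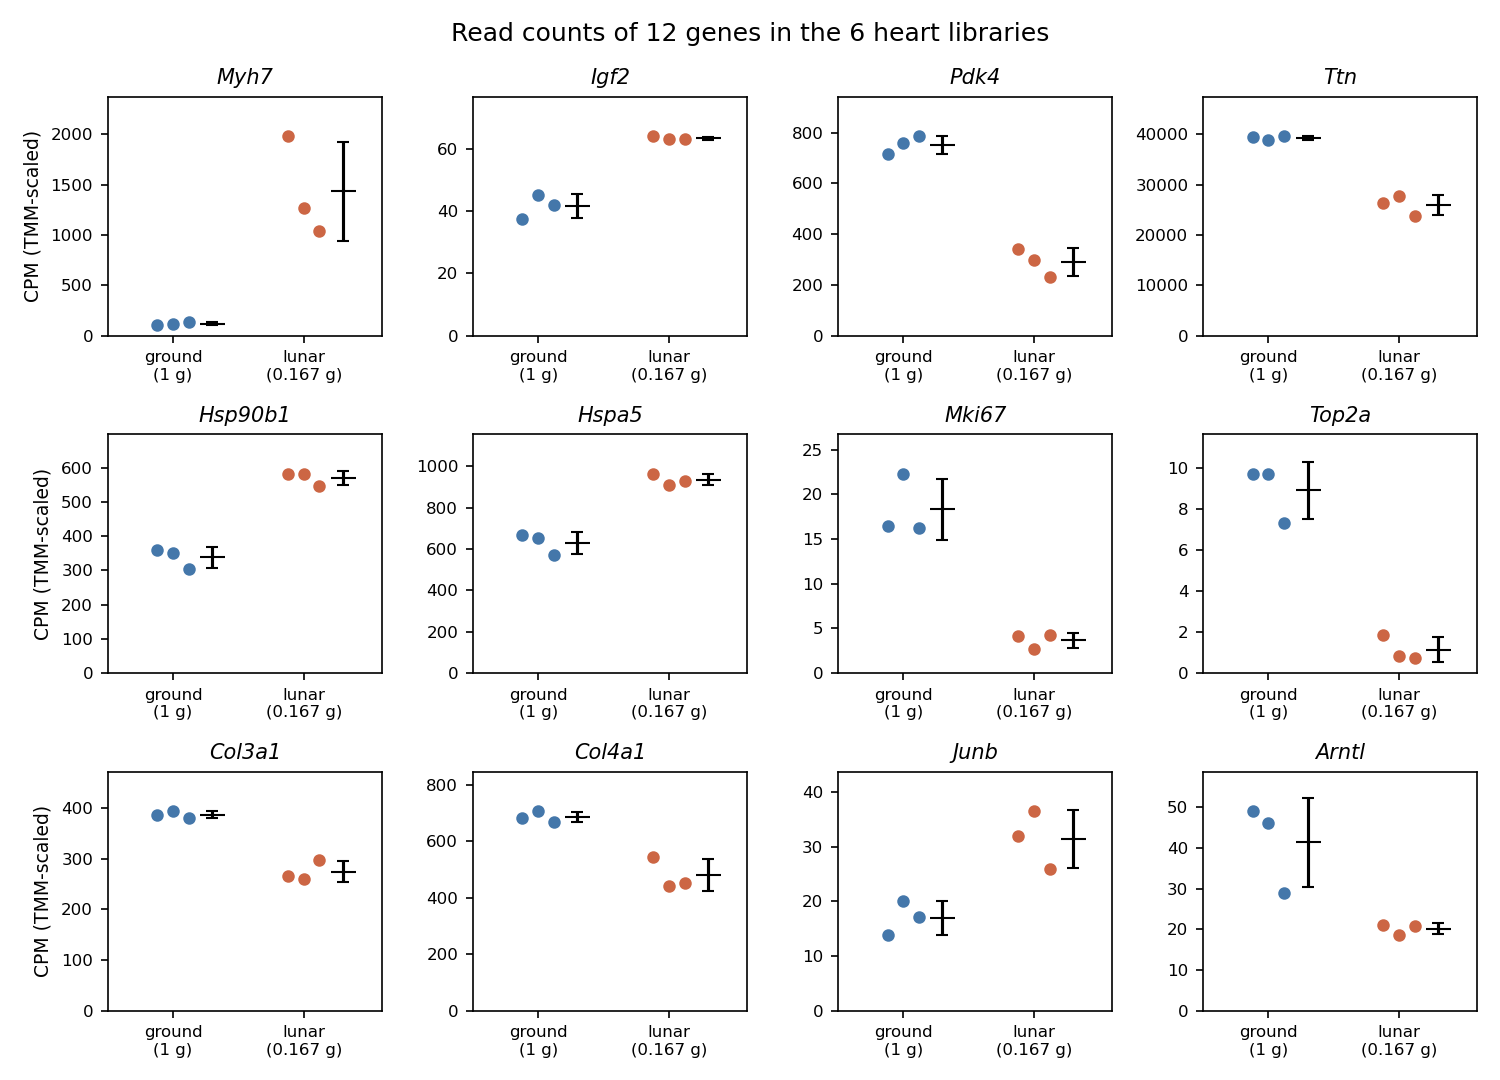
Normalised read counts (CPM, TMM-scaled, linear axes from 0) of 12 genes, chosen after their values were seen, in each of the 3 ground control (blue) and 3 lunar gravity (orange) libraries, with the mean and SD in black beside the points. Hsp90b1 went from 338 to 571 CPM and Mki67 from 18.3 to 3.66 CPM, with no overlap between the groups.

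Collagen and extracellular matrix genes had 13 of 38 tested members lower and none higher. Adjusted over the list alone, 18 were lower and 2 higher. Col3a1, a fibrillar collagen (ENSMUSG00000026043, chromosome 1, 45311538 to 45349706), fell from 386 ± 6.96 to 274 ± 20.6 CPM, a log2 fold change of -0.49 (SE 0.057, adjusted p = 8.40e-06). The basement membrane collagens Col4a1 and Col4a2 were 1.43-fold and 1.35-fold lower (adjusted p = 1.43e-04 and 5.14e-05). The type I collagens Col1a1 and Col1a2 had log2 fold changes of -0.24 and -0.27 (adjusted p = 0.013 and 0.0069). The list had 8 members lower without GC1, 5 without GC2 and 7 without LG2. Both type I calls were lost without GC1, GC2 or LG2, at up to 0.11 and 0.064. The list's median log2 fold change was -0.22 and its camera adjusted p was 4.88e-11, but adjusted p = 0.26 with an estimated correlation (4.03e-13 to 0.26 over all alternatives). Among 16 fibroblast markers 3 fell, and these were the collagens Col3a1, Col1a1 and Col1a2, also when adjusted over the list alone, and 1 fell without GC1, GC2 or LG2. That list did not pass (camera adjusted p = 0.078) but did without LG1 or LG3 (0.032 and 0.034).

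Of 22 adult sarcomere genes tested, 5 fell and 2 rose; adjusted over the list alone, 6 fell and 4 rose. Ttn, the giant spring protein of muscle, was 1.51-fold lower, at 39309 ± 390 against 25999 ± 1984 CPM (adjusted p = 1.17e-06). Its log2 fold change stayed between -0.64 and -0.54 with any 1 library left out, but was as weak as -0.19 among the other alternatives. Myh6, the main myosin heavy chain of the adult mouse heart, was 1.28-fold lower (adjusted p = 3.74e-04). Actc1, cardiac actin, was 1.72-fold lower (adjusted p = 0.0011; 0.069 without LG3). Myom2, a protein of the sarcomere's M-band, rose 2.07-fold (adjusted p = 0.012; 0.092 without LG2). The other changed members, chosen after their values were seen, were the myosin kinase Mylk3 (log2 fold change 0.34), the myosin gene Myh7b (-0.39, with adjusted p = 0.071 without GC1) and the Z-disc gene Ldb3 (-0.20). Ldb3 lost the call without any library but LG2, at up to 0.19. Ldb3 also lost it with upper quartile or total-count scaling, DESeq2 without independent filtering, non-robust fitting, total exon reads or the length trend removed, at up to 0.088. A replicate block cost it the call as well (0.052, or 0.0501 with the length trend removed too). The list had a camera adjusted p of 0.12 and passed toward lower without LG2 (0.0020). Without GC1, 3 members fell; without LG2, 1 rose, and without LG3, 4 rose.

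Myh7, the slow and fetal myosin heavy chain (ENSMUSG00000053093, chromosome 14, 54970688 to 54994634), had the largest rise among the named genes. It went from 119 ± 15.4 to 1431 ± 488 CPM, a log2 fold change of 3.59 (SE 0.33, adjusted p = 0.015). With any 1 library left out, that value stayed between 3.29 and 3.78, but the call was lost without GC1, GC2, GC3 or LG2, at up to 0.099. Among the other alternatives, 3 also lost the Myh7 call, at up to 0.53. Acta1, skeletal actin, was 1.95-fold lower (adjusted p = 0.0039), and 44.8% of its exon reads were unique. Of 13 fetal and hypertrophy genes tested, these were the 1 that rose and the 1 that fell, and 3 rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.89; 0.0029 toward lower under the deposited grouping of GC3). Without GC3, 4 members fell. Nppa and Nppb, which encode the natriuretic peptides, had log2 fold changes of 0.039 and -0.67 (adjusted p = 0.84 and 0.45). Nppb lay at 253 and 185 CPM in GC1 and GC2 and at 114 in GC3, and it passed as lower without GC3 (adjusted p = 0.0044), with non-robust fitting of all libraries (0.037) and under the deposited grouping of GC3 (7.03e-04).

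Calcium handling genes had 5 of 16 tested members lower and 1 higher, or 6 lower and 2 higher when adjusted over the list alone. Ryr2, the calcium release channel, was 1.28-fold lower (adjusted p = 2.91e-04), and Hrc, a calcium-binding protein of the sarcoplasmic reticulum, was 1.22-fold lower (adjusted p = 0.0017). Atp2a2, the calcium pump, was 1.16-fold lower (adjusted p = 0.021), a call lost without GC1, GC2 or GC3 (0.19). Pln, the pump's inhibitor, rose 1.23-fold (adjusted p = 0.0018), although only 14.8% of its exon reads were unique. Casq2 and Asph, chosen after their values were seen, had log2 fold changes of -0.31 and -0.26, and Asph lost the call without LG2 (0.073) and with the length trend removed (0.056). The list's camera adjusted p was 0.0056, but adjusted p = 0.73 with an estimated correlation. Over all alternatives it ranged from 1.91e-04 to 0.73, and the call was also lost without LG1 and under the deposited grouping of GC3 (0.14 each). Of 20 cardiac ion channel and gap junction genes, 1 rose, the potassium channel Kcna5, at 1.33-fold (adjusted p = 0.036), with 2 higher when adjusted over the list alone (camera adjusted p = 0.89, toward higher with a median of -0.043). Its call was lost without any library but LG1 (0.21).

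Fatty acid uptake and oxidation genes moved in both directions, with 2 of 30 tested members higher and 3 lower, or 4 higher and 5 lower when adjusted over the list alone (camera adjusted p = 0.89, toward lower with a median of 0.0063). Without GC1, 5 members fell, and without LG1, 4 rose. The oxidation enzyme Eci1 rose 1.28-fold (adjusted p = 0.0013). Pdk4, a kinase that restrains pyruvate oxidation, was 2.60-fold lower, at 753 ± 35.2 against 290 ± 54.5 CPM (adjusted p = 0.0089; 0.075 without LG2). The lipid droplet gene Plin5 was 1.53-fold lower (adjusted p = 1.55e-04), and Acsl1, which activates fatty acids, was 1.25-fold lower (adjusted p = 0.0023).

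Glycolysis genes had 3 of 23 tested members lower and none higher, with 8 lower and 1 higher when adjusted over the list alone. There was 1 lower member without GC2 and there were 6 without GC3. The 3 were Eno3, Pkm and Eno1, at 1.21-fold, 1.18-fold and 1.23-fold lower. Pkm lost the call without GC2 (0.086) and Eno1, with 33.5% of its exon reads unique, without GC2 or LG1 (0.11). The list's camera adjusted p was 0.0070 (0.051 without LG1), but adjusted p = 0.50 with an estimated correlation (7.94e-04 to 0.50 over all alternatives). Nuclear oxidative phosphorylation genes had 0 of 45 members past edgeR's test, with 8 at an unadjusted p under 0.05 and 0 by DESeq2 or limma voom (camera adjusted p = 0.82), though 2 were higher without LG1 and 1 lower without LG3. The smallest p was that of Ndufv1, a subunit of complex I, at 1.11-fold (adjusted p = 0.12; 0.025 with library totals). Of 13 mitochondrially encoded genes, mt-Nd3 passed at 1.18-fold (adjusted p = 0.049), also when adjusted over the list alone (camera adjusted p = 0.58), but 3.49% of its exon reads were unique and its log2 fold change was -0.0030 when all exon reads were counted. Its call was lost without any library but LG1 (0.26), and mt-Nd3 also lost it with DESeq2 (0.068), limma voom (0.066), non-robust fitting (0.080), unique exon reads (0.051), the 5 CPM filter (0.054) and the length trend removed (0.081). Lipid and cholesterol synthesis genes had 0 of 23 members past edgeR's test, with 3 at an unadjusted p under 0.05 and 0 by DESeq2 or limma voom (camera adjusted p = 0.82, toward higher with a median of -0.021). Acacb, an acetyl-CoA carboxylase, came nearest at 1.14-fold (adjusted p = 0.061) and passed without LG3 (0.011), with upper quartile scaling (0.044), library totals (0.021) or no filter (0.0086), and with the length or GC content trend removed (0.023 and 0.037).

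**Figure D2:**
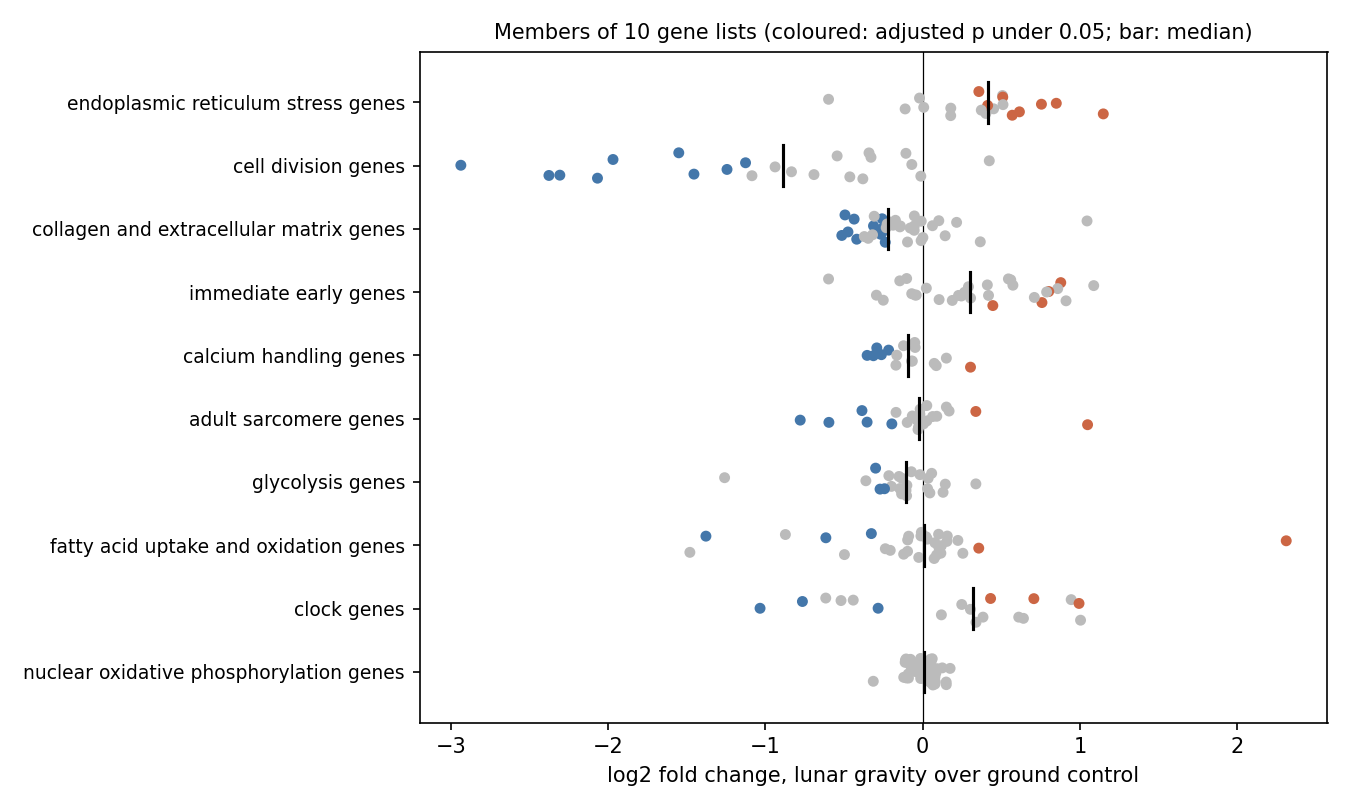
Log2 fold change of each tested member of 10 gene lists, chosen for display after their values were seen, with members past adjusted p 0.05 in orange (higher) or blue (lower), the others in grey, and a black bar at each list's median. Endoplasmic reticulum stress genes centre at 0.41 and cell division genes at -0.89.

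Immediate early genes, which are induced within minutes of a stimulus, had 4 of 30 tested members higher and none lower, and 15 higher and 1 lower when adjusted over the list alone. Junb, a subunit of the transcription factor AP-1, rose 1.84-fold (adjusted p = 0.0011), Ier2 rose 1.74-fold (adjusted p = 8.82e-04) and Klf4 rose 1.36-fold (adjusted p = 0.0041; 0.051 without LG2). Fos, chosen after its values were seen, had a log2 fold change of 0.76 (adjusted p = 0.0089; 0.065 without LG2). The list had 9 members higher without GC1, 7 without LG3 and 2 without LG2. Its median log2 fold change was 0.30 and its camera adjusted p was 8.26e-09, but adjusted p = 0.26 with an estimated correlation. Over all alternatives it ranged from 7.91e-16 to 0.41, the latter under the deposited grouping of GC3.

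Insulin and IGF signalling genes had 3 of 20 tested members higher and none lower, or 4 higher when adjusted over the list alone, and 1 higher without GC1 or LG2. The growth factor gene Igf2 rose 1.52-fold, from 41.6 ± 3.81 to 63.5 ± 0.535 CPM (adjusted p = 4.94e-05). The IGF-binding proteins Igfbp5 and Igfbp3 rose 1.23-fold and 1.41-fold. Igfbp5 lost the call without GC1, GC3, LG2 or LG3 (0.11) and Igfbp3 without GC1, GC2, LG1 or LG2 (0.16). The list's camera adjusted p was 0.0097 (0.073 without LG1, 0.14 under the deposited grouping of GC3), but adjusted p = 0.44 with an estimated correlation (5.06e-04 to 0.44 over all alternatives). Of 40 cytosolic ribosomal protein genes, 33 had a log2 fold change above 0, at a list median of 0.12. Only Rpl30 passed over all genes, at a log2 fold change of 0.26 (adjusted p = 0.043), and none when adjusted over the list alone. With 28.0% of its exon reads unique, Rpl30 lost the call without any library but LG1 (0.21) and with DESeq2 (0.091; 0.16 without independent filtering), limma voom (0.051), non-robust fitting (0.054), total or unique exon reads (0.12 and 0.62) and the length trend removed (0.056). DESeq2 and limma voom each called 0 ribosomal members. The ribosomal list's camera adjusted p was 6.95e-05, but adjusted p = 0.26 with an estimated correlation (8.51e-07 to 0.26 over all alternatives).

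Clock genes had 3 of 18 tested members higher and 3 lower, with 7 higher and 3 lower when adjusted over the list alone. Arntl (BMAL1), a core activator of the circadian clock, was 2.05-fold lower, at 41.4 ± 10.9 against 20.1 ± 1.39 CPM (adjusted p = 0.023). Npas2 and Clock, which pair with it, were 1.70-fold and 1.22-fold lower (adjusted p = 0.0031 and 0.024). Per3, of the repressor family, rose 1.99-fold (adjusted p = 0.037), with 39.1% of its exon reads unique. Tef and Hlf, clock output factors chosen after their values were seen, had log2 fold changes of 0.71 and 0.43. GC3 lay apart from its group here, with Arntl at 28.9 CPM against 49.0 and 46.3 in GC1 and GC2. Calls were lost by Arntl (without GC2, LG1, LG2 or LG3; 0.19), Clock and Per3 (each without GC1, GC2, LG1 or LG2; 0.20 and 0.15), Tef (GC1, LG1 or LG2; 0.21) and Hlf (GC2, GC3, LG1 or LG2; 0.23). Clock also lost it with library totals (0.062) or the length trend removed (0.097), and Per3 with total exon reads (0.22). Tef lost it with a replicate block (0.24, or 0.22 with the length trend removed too). Hlf lost it with DESeq2 (0.062; 0.11 without independent filtering), limma voom (0.051) and non-robust fitting (0.057), and Arntl with limma voom (0.075). DESeq2, which gave an adjusted p to 12 of the 18 members, called 3, and limma voom called 4. The list had a camera adjusted p of 0.080 and passed toward higher without GC1 (0.032), LG3 (0.0031) or a filter (0.045). It had 5 members lower without GC3 and 1 without GC2, LG1 or LG2, and 5 higher without LG3, 1 without GC2 and 0 without LG1 or LG2.

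Glucocorticoid response genes had 2 of 19 tested members higher and 3 lower, or 3 of each when adjusted over the list alone (camera adjusted p = 0.93). Lcn2, an iron-scavenging protein, rose 2.76-fold (adjusted p = 0.0020) and the sulphotransferase Sult1a1 rose 1.63-fold (adjusted p = 6.10e-04). Pdk4, Cdkn1a and Mt1 fell, and 1 member fell without LG1, LG2 or LG3. The metallothionein Mt1 (log2 fold change -0.25, chosen after its values were seen) lost the call without any library but LG2 (0.19) and with upper quartile or total-count scaling, DESeq2 with or without independent filtering, or non-robust fitting, at up to 0.14. Cdkn1a, the cell cycle inhibitor p21, was also the 1 changed member of 18 p53 target genes, at 2.78-fold lower (adjusted p = 0.012). That call was lost without LG1, LG2 or LG3 (0.11). Adjusted over the list alone, 1 p53 target was higher and 2 were lower (camera adjusted p = 0.89, toward lower with a median of 0.070).

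Antioxidant response genes had 2 of 24 tested members higher and 1 lower, or 4 and 1 when adjusted over the list alone. Gstm1, a glutathione transferase, rose 1.22-fold (adjusted p = 0.0044), the quinone reductase Nqo1 rose 1.34-fold (adjusted p = 0.0054; 0.083 without GC2), and mitochondrial superoxide dismutase Sod2 was 1.16-fold lower (adjusted p = 0.020), a call lost without GC1, GC2 or LG1 (0.15). The list had a camera adjusted p of 0.058 and passed toward higher with upper quartile scaling (0.046), library totals (0.031), no filter (0.0071), the 1 CPM filter (0.037), unique exon reads (0.040), the GC content trend removed (0.047) and without GC2 (0.023). Atrophy, proteasome and autophagy genes had 3 of 28 members higher and 1 lower, or 4 and 1 when adjusted over the list alone (camera adjusted p = 0.073; toward higher 0.038 with library totals, 0.044 without a filter and 0.017 without LG3, where 6 members rose). The autophagy genes Bnip3 and Map1lc3b had log2 fold changes of 0.35 and 0.38, with 30.1% and 13.9% of exon reads unique, and Map1lc3b lost the call on unique exon reads alone. The muscle F-box gene Fbxo40 was 1.17-fold lower, a call Fbxo40 lost without GC1, GC2 or LG2 (0.16) and with library totals (0.081). Eif4ebp1, chosen after its values were seen (log2 fold change 0.35), lost its call without GC1, GC2, LG1 or LG2 (0.22) and with DESeq2 with or without independent filtering, non-robust fitting or the length trend removed, at up to 0.13. The muscle ubiquitin ligases Fbxo32 and Trim63 did not pass, at 1.23-fold and 1.06-fold (adjusted p = 0.37 and 0.58), though Fbxo32 passed without a filter (0.0013) and its groups did not overlap.

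Hypoxia response genes had 2 of 20 tested members higher, Bnip3 and Hif1a, and 2 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.82), and 3 lower without GC3. Hif1a, the hypoxia-inducible factor, rose 1.23-fold (adjusted p = 0.040), a call lost without any library but GC3 (0.23). Hif1a also lost it with DESeq2 (0.077), non-robust fitting (0.056) and total exon reads (0.13). Mechanosensitive YAP and SRF target genes had 2 of 24 members higher and 2 lower, or 4 and 3 when adjusted over the list alone (camera adjusted p = 0.79). F3, tissue factor, and the actin-binding Tagln rose 1.43-fold and 1.36-fold, with calls lost without GC2 or LG2 (0.094) and without GC1 or LG3 (0.068). Smooth muscle actin Acta2 was 1.26-fold lower, and Cyr61, chosen after its values were seen, had a log2 fold change of -0.29. Acta2 lost the call without any library but LG3 (0.13) and Cyr61 without any but LG1 (0.23). Cyr61 also lost it with library totals, DESeq2 with or without independent filtering, or non-robust fitting, at up to 0.12. Adrenergic and natriuretic signalling genes had 1 of 26 members higher and 1 lower, also when adjusted over the list alone (camera adjusted p = 0.82, toward higher with a median of -0.0019). These were the receptor kinase Grk5, at 1.34-fold (adjusted p = 0.0027), and the angiotensin-converting enzyme Ace, at 1.45-fold lower (adjusted p = 1.43e-04).

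Inflammation genes had 1 of 16 tested members higher, the chemokine Cxcl14, at 1.44-fold (adjusted p = 0.042), both over all genes and adjusted over the list alone. Cxcl14 lost the call without any library but GC1 (0.24) and with the length trend removed (0.056), and the list, with a camera adjusted p of 0.21, passed toward higher without GC2 (0.024). Interferon response genes had 0 of 25 members past edgeR's test, with 1 at an unadjusted p under 0.05, 0 by limma voom and 0 by DESeq2, which gave an adjusted p to 4. That member was Bst2, tetherin, with a log2 fold change of -0.53 (adjusted p = 0.18). The interferon list, with a camera adjusted p of 0.51, passed toward lower without LG1 (0.0032), and 1 member rose without GC2. Of 24 RNA splicing regulator genes, 1 fell, Hnrnpa2b1, at 1.17-fold lower, also when adjusted over the list alone (camera adjusted p = 0.68). Hnrnpa2b1 lost this call without GC1, GC2, LG1 or LG2 (0.21) and with library totals (0.090), non-robust fitting (0.057) or the length trend removed (0.051). Of 8 cold-inducible and hibernation-type genes, 2 rose, also when adjusted over the list alone: Hspa5 and the calcium pump regulator Sln, at 1.31-fold (adjusted p = 6.56e-04). That list's median was -0.078 while camera's direction was up (adjusted p = 0.22).

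Several of the 12 largest rises belonged to genes at or below 6.90 CPM in lunar gravity. Cox6b2, a cytochrome oxidase subunit, rose 3.53-fold, Stox1 2.83-fold, Nmrk2, a kinase of NAD synthesis, 2.30-fold, Ms4a6d 2.21-fold and Ifit1bl1 1.86-fold. Only 12.3% of the exon reads of Nmrk2 were unique, and its log2 fold change was 0.12 (adjusted p = 0.57) when all exon reads were counted. Calls were lost by Cox6b2 (without GC2, GC3, LG2 or LG3; 0.15), Stox1 (GC1, GC3, LG1 or LG3; 0.10), Ifit1bl1 (GC1, GC2, LG2 or LG3; 0.17) and Ms4a6d (any 1 library; 0.13). Ifit1bl1 also lost it with non-robust fitting (0.052) and total exon reads (0.062).

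Of the RNA quality lists, abundant non-coding RNAs had 3 of 4 tested members lower, or 4 when adjusted over the list alone. The nuclear RNAs Malat1 and Neat1 were 1.36-fold and 1.34-fold lower (adjusted p = 8.40e-06 and 4.58e-04). Lars2, a mitochondrial tRNA synthetase gene kept in this list, was 1.27-fold lower, a call lost without GC2, GC3 or LG2 (0.078). Replication-dependent histone genes had 0 of 7 members past edgeR's test, with 0 at an unadjusted p under 0.05 and 0 by DESeq2 or limma voom (camera adjusted p = 0.89), and 1 rose without LG1. Intron reads made up 37.3% ± 0.50 of the unique exon and intron reads in ground control and 33.4% ± 0.96 in lunar gravity (n = 3 each), with mitochondrial genes left out. All lunar gravity libraries lay below all ground controls (exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 allows). This share moved with the groups.

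**Figure D3:**
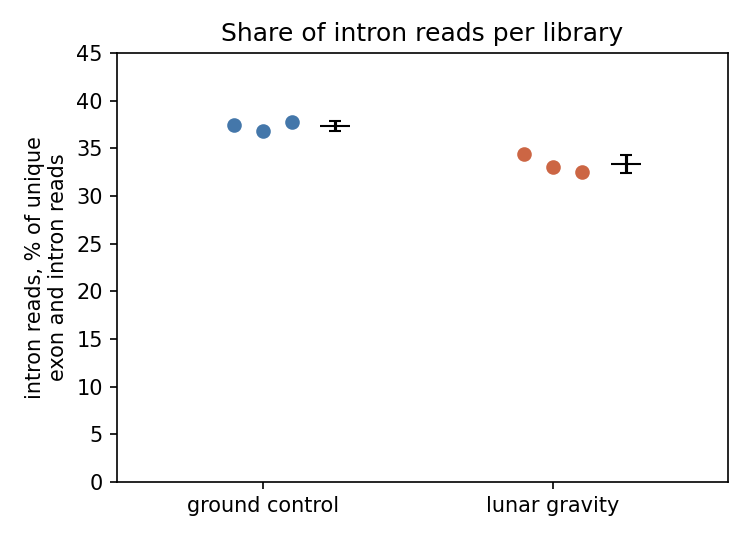
Intron reads as a percentage of unique exon and intron reads, mitochondrial genes left out, in each library (points), with the group mean and SD in black. The lunar gravity libraries averaged 33.4% and the ground controls 37.3%.

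Among the heart muscle markers, ventricular markers had 2 of 11 tested members lower (Myh6 and Actc1) and 1 higher, the transcription factor Irx4 at 1.26-fold, with 3 lower and 1 higher adjusted over the list alone. The Irx4 call was lost without any library but LG1 (0.21) and with DESeq2 (0.089). This list's camera adjusted p was 0.066, and it passed toward lower without GC2 or LG2 (0.044 and 0.0036), without a filter (0.048) and with the length trend removed (0.015). Atrial markers had 3 of 13 members higher, Dkk3 at 1.37-fold (adjusted p = 1.88e-04), Sln and Kcna5, and 5 higher and 4 lower when adjusted over the list alone (camera adjusted p = 0.12; 0.0499 without a filter). Without GC3, 2 members were lower. Conduction system markers had 0 of 7 members past edgeR's test, with 3 at an unadjusted p under 0.05, 2 lower when adjusted over the list alone, and 0 by DESeq2 or limma voom. Without LG1, 1 member fell. All 7 had a log2 fold change below 0, and the camera adjusted p was 0.0097 (0.073 without LG1, 0.12 under the deposited grouping of GC3), but adjusted p = 0.26 with an estimated correlation (0.0029 to 0.26 over all alternatives). Of 5 skeletal muscle markers, Acta1 fell, also when adjusted over the list alone, and the camera adjusted p toward lower was 0.012, but adjusted p = 0.26 with an estimated correlation (5.82e-05 to 0.76 over all alternatives). This list did not pass without GC3 or LG3 (0.092 and 0.096), nor under the deposited grouping of GC3 (0.76) or without a filter (0.35), where its median was 0.17 in place of -0.28.

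Endothelial markers had 0 of 18 members past edgeR's test, with 6 at an unadjusted p under 0.05 and 0 by DESeq2 or limma voom (camera adjusted p = 0.88; 0.032 toward lower without LG1); 1 member fell without LG3. Smooth muscle and pericyte markers had 2 of 15 members higher and 2 lower, or 3 and 2 when adjusted over the list alone (camera adjusted p = 0.82). The pericyte gene Rgs5 rose by a log2 fold change of 0.26 (0.093 without GC2) and Synpo2 was 1.19-fold lower (0.098 without GC1 or GC2), beside Tagln and Acta2. Lymphatic endothelial (7 tested), mesothelial and epicardial (5), and Schwann and neuronal markers (9) had 0 members changed by edgeR, DESeq2 or limma voom and 0 at an unadjusted p under 0.05, with camera adjusted p of 0.58, 0.89 and 0.89. Cartilage and valve markers had 0 of 7 changed by any of these tools and 1 at an unadjusted p under 0.05 (camera adjusted p = 0.27).

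Among blood and immune markers, macrophage markers had 0 of 16 members past edgeR's test, with 1 at an unadjusted p under 0.05 and 0 by DESeq2 or limma voom (camera adjusted p = 0.51; 0.017 toward lower without LG1, where 1 member fell). Red blood cell markers had 0 of 10 changed by edgeR, DESeq2 or limma voom and 0 at an unadjusted p under 0.05 (camera adjusted p = 0.27; toward lower 3.48e-07 without LG3, where 1 member fell, and 0.0062 under the deposited grouping of GC3). Their summed level was 1231 CPM in LG3 and 800 and 780 CPM in LG1 and LG2. Platelet markers had 0 of 6 changed by these tools and 0 at an unadjusted p under 0.05 (camera adjusted p = 0.28; 0.040 toward higher without GC2). Lists with under 5 tested members had no camera test. Of these, neutrophil markers had 1 of 4 higher, Lcn2, while T lymphocyte (1 tested), B lymphocyte (4), mast cell (2) and thymus markers (2) had 0 changed by edgeR, DESeq2 or limma voom, with 1 B lymphocyte and 1 thymus marker at an unadjusted p under 0.05.

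White adipose markers had 2 of 9 tested members higher and 1 lower, or 2 of each when adjusted over the list alone (camera adjusted p = 0.34; 0.0499 without a filter). The lipase genes Pnpla2 and Lpl had log2 fold changes of 0.50 and 0.20 (adjusted p = 1.32e-04 and 0.025), and the lipid droplet gene Plin4 had a log2 fold change of -0.26 (adjusted p = 0.029). Lpl lost the call without GC1, GC2, GC3 or LG2 (0.15) and Plin4 without GC1, GC2, GC3 or LG3 (0.12) and with library totals (0.090). Brown adipose markers had 0 of 7 changed by edgeR, DESeq2 or limma voom, with 1 at an unadjusted p under 0.05 (camera adjusted p = 0.55). No lung and airway marker had counts enough to test. Of 3 liver markers tested, Ahsg was 2.17-fold lower (adjusted p = 0.023), a call lost without any library but GC3 (0.20) and with limma voom (0.074). The summed liver markers stood at 169 CPM in GC2, against 30.5 and 19.0 in GC1 and GC3 and 22.8, 8.04 and 6.83 in LG1 to LG3.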

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

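The length and GC content corrections, the comparison of intron shares, and the scaling and left-out libraries of the intron counts were chosen after the lower genes and the lower intron share had been seen, and the splits of the libraries were set before their results were seen.

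Intron reads, which the comparison of exon counts leaves aside, also differed between the groups. Of 11765 genes with enough intron reads to test, 341 changed by edgeR's quasi-likelihood test, 43 higher and 298 lower in lunar gravity. The intron reads of Ttn and Ryr2, both long muscle genes, had log2 fold changes of -1.34 and -1.18 (SE 0.098 and 0.087), against -0.60 and -0.35 in exons. Myh6 gave -0.85 in introns and -0.35 in exons. Myh7, which rose by 3.59 in exons, gave -0.87 in introns. As the use of strand is not stated, reads of an antisense or overlapping RNA are not told apart from those of Myh7's own introns. These intron values were scaled on intron reads alone, so a drop shared by most intron counts is not in them. Scaled by exon reads, the introns of Ttn, Ryr2, Myh6 and Myh7 gave -1.49, -1.33, -1.01 and -1.02. Of 395 genes changed in exon counts and tested here, 58 also changed in intron reads, 55 of them in the same direction. Scaling by exon reads gave 850 genes, 18 higher and 832 lower. The count was 547 without GC1, 147 without GC2, 339 without GC3, 198 without LG1, 172 without LG2 and 226 without LG3. In 1 of the 10 splits of the 6 libraries into 3 and 3, the real one, as many intron genes were called (341, against at most 1 in the others), and 10 splits are too few for a share under 0.05.

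The genes lower in lunar gravity were also longer, with a median exon length of 5135 bases against 4179 for all tested genes and 3242 for the higher genes. A length trend between libraries, as uneven RNA integrity can leave, was removed: the median log2 fold change of the 271 lower genes was -0.38 before and -0.37 after (quartiles -0.59 to -0.27), and 242 kept the call. The removal moved the log2 fold change of the lower genes by a median of 0.015, and of all tested genes by up to 0.42. The kept median argues against a length trend as the whole cause for the lower genes as a set, but not for each gene. Almost no GC content trend was there to remove (Spearman -0.0078 with log2 fold change): its removal moved no gene by more than 0.051 and left the median at -0.37 with 264 still called, so the kept calls say little, but a trend of that size is too small to be the whole cause. For less unspliced RNA counted in exons as the cause, the prediction was a larger intron share in the lower genes than in genes of like expression. The median difference was -1.67 percentage points (bootstrap interval -4.98 to 0.81, quartiles over genes -16.6 to 17). This share was pooled over the 6 libraries and not divided by intron length. It thus does not decide whether less unspliced RNA lowered the exon counts. The lower genes did hold a larger median intron share than the higher genes, at 22.5% against 14%. Lower transcription, a lower yield of nuclear RNA, and other differences between station and ground handling stay open and were not tested.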

How the results depend on the processing

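The 5 CPM filter, other read columns, DESeq2 without independent filtering, deposited grouping, length and GC corrections (with the block too) and intron alternatives were chosen after seeing the data. Against 462 changed genes (191 higher, 271 lower), 90 list members and 10 lists, library totals gave 288 higher genes. No filter gave 765 genes, 316 higher and 449 lower, 146 members and 17 lists; 74 of its 303 extra calls had not been tested before, and the cause of the rest was not tested. DESeq2 gave 307 genes, 177 lower, of which 287 were shared with edgeR. Its independent filtering left 6417 genes, 99 of them called by edgeR, with no adjusted p; without that filtering it gave 286 genes, 122 higher and 164 lower, so the filtering does not account for the lower count, and the cause was not tested. With GC3 grouped as deposited, groups of 2 and 4 gave 32 genes, 5 higher and 27 lower, and 14 members, 13 genes being shared. Adjusted p under 0.1 gave 290 higher genes; under 0.01 it gave 212 genes, 78 higher and 134 lower. A 2-fold limit gave 43 genes, 10 higher and 33 lower. Lists numbered 0 with an estimated correlation and 3 with fry. The estimate was 0.44 for calcium handling and 0.38 for endoplasmic reticulum stress genes. For cell division and ribosomal protein genes it was 0.026 and 0.027, near the preset 0.01. Yet camera's unadjusted p went from 1.59e-19 to 0.0013 and from 7.73e-06 to 0.021. A list lost in this way need not have strongly correlated members. With the correlation estimated, camera also tests on the residual degrees of freedom of the 6 libraries. With a preset correlation it tests on far more. How much of each loss this accounts for was not tested. No shared call changed sign under any alternative. RLE and upper quartile scaling, the 1 and 5 CPM filters, limma voom, non-robust fitting, other exon read columns, trend corrections and leaving out mitochondrial and ribosomal RNA genes gave 431 to 478 changed genes. Alternatives for a table without counts were not run.

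Leaving out 1 library gave 219 to 463 changed genes (219 without GC2, 232 without LG2), 86 to 190 higher, 132 to 273 lower, 57 to 100 members (57 without GC2, 58 without LG2), 10 to 15 lists (15 without GC2) and 147 to 547 intron genes. Of 86 named genes called, 43 lost the call in at least 1 of these fits, and 40 lost it only under the deposited grouping. DESeq2 cost 4 of these calls, DESeq2 without independent filtering 19, the deposited grouping 83, and every other alternative at most 5. Direction turned for mt-Nd3 with total exon reads (-0.0030) and for Nppa, never called: -0.048 under the deposited grouping, -0.012 without GC3 and -0.016 without LG2, with a range of -0.016 to 0.11 over left-out libraries. The cause was not tested.

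The labels do not say whether the shared numbers 1 to 3 pair the libraries, and the counts gave no sign of it. Same-numbered deviations correlated at 0.0026, -0.054 and 0.048, none over 0.1. Of the lunar gravity libraries only LG3 correlated best with its own number. A replicate block gave 545 genes, 227 higher and 318 lower, 111 members and 10 lists, and 555 genes with the length trend removed too. On simulated counts the block made 12% false calls, against 6.21% without it. Those counts were drawn with no replicate effect, so this cannot tell whether the real libraries are paired.

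The 10 splits into 3 and 3 are too few for a share under 0.05. The real split gave 462 genes and 90 members, against at most 4 and 1 in the others (1 split of 10 as large for each). It gave 10 lists, and the others gave 9, 1, 4, 5, 7, 13, 9, 9 and 9 (2 splits of 10 as large). The count of lists thus does not set the real split apart. Simulation recovered 30% of 1.3-fold changes, so small changes may be missed.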

Other observations

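The tests on GC3 and on the clock genes were chosen after the values were seen.

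Several liver transcripts, chosen after their values were seen, had most of their counts in GC2. Alb, serum albumin, had 79, 641 and 45 counts in GC1 to GC3 and 58, 2 and 0 in LG1 to LG3. Serpina3k had 64 counts in GC2 and at most 5 elsewhere, and the fibrinogen gene Fgb had 43 in GC2 and at most 5 elsewhere. Ahsg, the 1 liver marker called changed, had 51, 78 and 31 counts in GC1 to GC3 and 32, 25 and 28 in LG1 to LG3, a more even spread.

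The header of the deposited table places GC3 with lunar gravity. In the authors' deposited table, 111 genes passed adjusted p 0.05, 16 with a positive and 95 with a negative fold change; 61 were tested here, 28 changed here, 10 belonged to the liver list and 10 to the clock list. A mislabelled lunar gravity sample was tested on 380 genes called without GC3. On a scale from 0 (mean of GC1 and GC2) to 1 (lunar gravity mean), its median position was 0.21 (quartiles -0.0088 to 0.50), and 75.3% of the genes lay nearer ground control. Held out alike, GC1 and GC2 lay at 0.10 and 0.060 and LG1 to LG3 at 0.88, 0.92 and 0.69. This argues against a wrong label. In all 49585 genes the deposited GC mean equalled that of GC1 and GC2, and the PG mean that of GC3 and LG1 to LG3. All 32 genes called here under that grouping were among the 111. The deposited means thus counted GC3 with lunar gravity, and not the header alone. Why GC3 was placed there was not tested.

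Over 9 clock genes called without it, GC3 lay at a median of 0.63 (quartiles 0.50 to 0.76), against 0.20 over the 371 other genes. These 371 are part of the 380 genes used above, so they add no separate evidence on the label. LG3 lay at 0.49 over 7 clock genes called without it. The position of GC3 in clock genes had been seen before it was measured, so it does not bear on why they differed. The labels give no collection time, and hearts collected at different times of day and an effect of the environment on the clock both stay open.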
